A study of Mus musculus with 12 samples.

How the data were processed

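Skin RNA of K14-CreERT mice with floxed Nedd8 or floxed Sumo2 was measured in 12 libraries, 3 Cre-negative and 3 Cre-positive per line, made with a 3′ tag kit (QuantSeq FWD) that reads the end of each transcript. The deposited tables, 1 per line, hold raw read counts for 56953 Ensembl genes, with no normalization by the authors. Per the submitters' processing notes the reads went through STAR, featureCounts and DESeq2, with no versions stated and with both GRCm38 and GRCm39 listed as genome builds. Of 51992 nuclear genes shared with GENCODE M21, an annotation of GRCm38, 1368 (2.63%) start at the same position, while 37 of 37 mitochondrial genes do, so the coordinates are not those of GRCm38. The strand setting, the handling of reads with several matches and any use of molecular identifiers are not given in the sources used here. Antisense and overlapping genes are therefore uncertain, and intervals and floors cover counting error only.

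Samples were grouped by the labels. The column headers of NEDD8 Cre-positive library 2 and of the SUMO2 library labelled Cre-positive 2 differ from their sample titles and were read as misspellings of them. In mega-counts (M), NEDD8 Cre-negative libraries 1 to 3 held 15.5, 15.4 and 10.8, and Cre-positive libraries 5.55, 9.81 and 34.4. The SUMO2 libraries labelled Cre-negative held 7.44, 7.29 and 7.66, and those labelled Cre-positive 5.18, 5.87 and 4.69. No pair of libraries was identical, and the lowest chi-square per gene between any pair was 6.96. Sex was read from Ddx3y and Xist.

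Each line was fitted alone with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM, robust quasi-likelihood F test, two-sided, Benjamini-Hochberg adjusted p under 0.05). The difference between the responses was tested as a contrast of 4 group means over all 12 libraries. SE is the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes. A group without counts was set to a floor of 3 counts over the group, and a group with 1 to 3 counts was given as a ratio with its 95% exact binomial interval. Of 1016 genes in 45 gene lists, 999 were found in the tables. Lists with at least 3 tested members, 42 in each line and 43 for the difference, went through camera of limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the lists tested, and again with an estimated correlation and with fry. List medians are those of the voom fit unless edgeR is named. Overlap was tested with Fisher's exact test, and Sumo2 reads with exact binomial and exact permutation tests. Copies of Sumo2 were sought with BLAST 2.17.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

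Tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Nedd8 and Sumo2, the 8 largest called rises and falls per line with non-overlapping groups and a mean of at least 20 counts in the higher group, up to 4 called members per list (the 2 most abundant where none was called), the 5 smallest p-values where no gene passed, and 5 genes per direction for the difference. A gene named in either line may be shown in both, and some genes that the rule names are not reported here. Alternatives were RLE and upper-quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, replicate numbers as blocks, omission of muscle, fat, hair and blood genes, all 12 libraries in a joint fit, and omission of each library in turn. Sex as a covariate, female-pattern libraries only, and the SUMO2 contrast taken with exchanged labels were added after the data were seen. In the NEDD8 line the deviations of equal replicate numbers from their group means correlated at 0.33, 0.12 and 0.20. Cre-negative 2 correlated slightly better with Cre-positive 3 (0.15) than with Cre-positive 2 (0.12). The numbers were still read as pairing these samples, a weak reading that comes from the data and not from the labels. The reported fits have no blocks, as planned.

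The tests were tried on simulated data with 200 changed genes in each design. After the filter on low counts 13842 (NEDD8), 12641 (SUMO2) and 13698 (difference) genes were tested. The shares found are of the changed genes that passed this filter. At 2-fold, 4-fold and 8-fold changes edgeR found 1.54%, 66.7% and 95.3% in the NEDD8 design, 9.09%, 74.2% and 93.3% in the SUMO2 design and 1.59%, 33.8% and 63.1% for the difference. It called 8, 9 and 4 unchanged genes, where DESeq2 called 30, 30 and 15. Camera called the shifted list in each design and 0 unchanged lists. The simulated genes were drawn independently of each other. The trial therefore does not show how often camera with the preset correlation calls unchanged lists of correlated genes. Groups of 3 were not tested for outlying values. No reads were used here, so exon usage of the floxed genes was not analysed.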

Results

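RNA of mouse skin was counted gene by gene in 12 libraries, 3 in each of 4 groups. The mice carried a floxed Nedd8 gene or a floxed Sumo2 gene, with or without K14-CreERT, a recombinase that is driven by the keratin 14 promoter of basal keratinocytes and works only after tamoxifen. Tamoxifen was put on the skin for 5 days, and the skin was taken after 5 more days. The columns of the NEDD8 table also carry the word DMSO, a solvent, which those of the SUMO2 table do not, and the labels do not explain it. NEDD8 and SUMO2 are small proteins that are joined to other proteins as ubiquitin is, and NEDD8 switches on the cullin-RING ubiquitin ligases. The 3′ tag libraries held 10.8 to 15.5 M counts (M for mega) in NEDD8 Cre-negative skin and 5.55 to 34.4 M in NEDD8 Cre-positive skin. They held 7.29 to 7.66 M in the SUMO2 libraries labelled Cre-negative and 4.69 to 5.87 M in those labelled Cre-positive. The labels do not say that replicates came from separate mice, so every p-value measures only the spread between samples. Values below are means ± SD over 3 libraries, in CPM, the count over the TMM-scaled library size in M, and coordinates are those of the deposited tables.

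The first question was whether each targeted gene lost its transcript. Nedd8 (chromosome 14, 55899720 to 55909581) stood at 374, 299 and 307 CPM in NEDD8 Cre-negative skin and at 410, 164 and 153 CPM in Cre-positive skin. The means were 327 ± 41.3 and 242 ± 146 CPM, a log2 fold change of -0.43 (SE 0.399, edgeR adjusted p = 0.429), so no loss passed the edgeR test. Limma-voom with quality weights, on the same 6 libraries, did call a fall (log2 fold change -0.851, adjusted p = 0.0183). Cre-positive library 1, at 410 CPM, decided the edgeR result. Without it, Nedd8 fell by 1.02 on the log2 scale with an edgeR adjusted p of 0.0028, and over all 17 alternatives the log2 fold change lay between -1.02 and -0.18 and the adjusted p between 0.0028 and 0.813. In that library 17.5% of all counts fell on the ribosomal gene Rn18s-rs5, and its TMM factor was 0.647. Scaled by library totals alone, Nedd8 stood at 265, 165 and 151 CPM in the Cre-positive libraries and at 415, 343 and 368 CPM in the Cre-negative ones. In the SUMO2 line Nedd8 stood at 437 ± 90 and 378 ± 9.69 CPM (edgeR adjusted p = 0.67).

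Sumo2 (chromosome 11, 115413928 to 115427102) gave almost no reads in any library. In the SUMO2 line the libraries labelled Cre-negative held 0, 0 and 1 Sumo2 reads, or 1 in 22.4 M, and the libraries labelled Cre-positive held 1, 5 and 3, or 9 in 15.7 M. The rate in the libraries labelled Cre-negative was thus 0.0781 times that in the libraries labelled Cre-positive (95% exact binomial interval 0.00178 to 0.564, two-sided exact binomial p = 0.00219). An exact permutation test of the 6 libraries gave p = 0.1, the smallest that 3 against 3 can give. In the NEDD8 line, where Sumo2 was not targeted, Cre-negative skin held 32 reads in 41.8 M and Cre-positive skin 20 in 49.7 M. The Cre-negative rate was 1.9 times the Cre-positive rate (1.06 to 3.51, exact binomial p = 0.0254, exact permutation p = 0.3). By label this lies opposite to the SUMO2 line. Turned round, as Cre-positive over Cre-negative, the NEDD8 ratio is 0.525 (0.285 to 0.947). The floxed exons are not given in the sources used here, and a 3′ tag may lie outside the deleted part, so the counts do not measure the deletion. BLAST found 14 other genes at least 90% identical to Sumo2 over at least 200 aligned bases (90.6% to 100%), of which 13 had 0 counts in every library and Samd8, 92.7% identical over 532 bases, had 5654. How reads with several matches were handled is not given, so Sumo2 reads may also have been lost to them. Sumo3, which encodes a near-identical protein, stood at 413 ± 95 CPM in the SUMO2 libraries labelled Cre-negative and 232 ± 32.6 CPM in those labelled Cre-positive (edgeR adjusted p = 0.21).

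**Figure D1:**
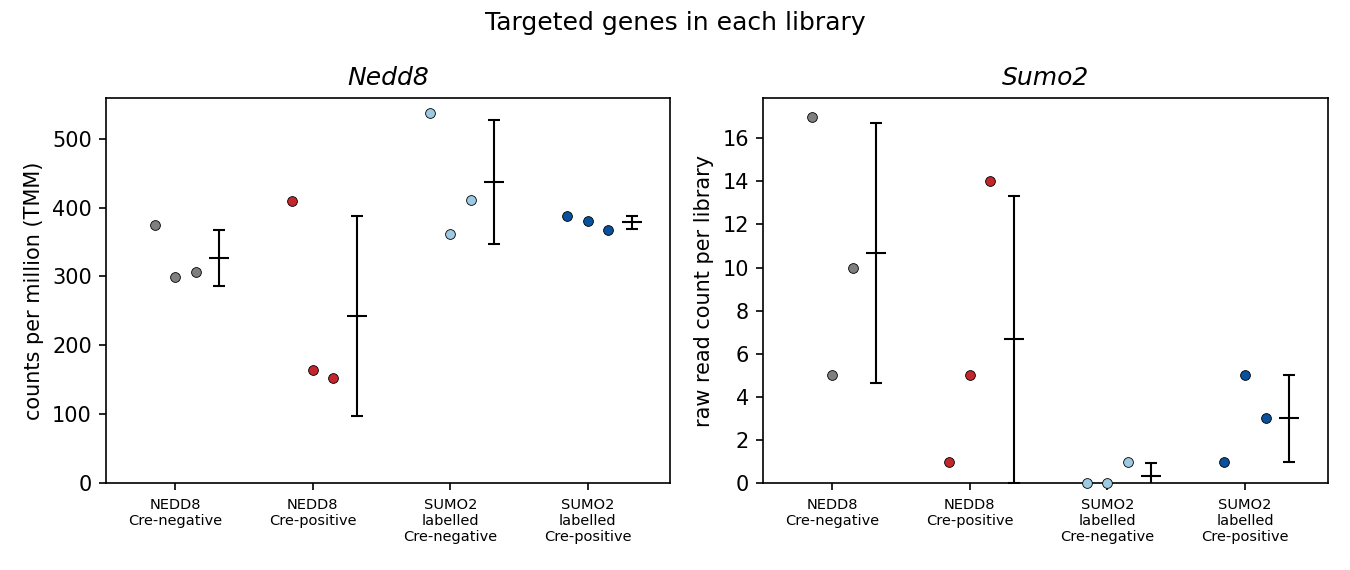
Nedd8 in CPM scaled by TMM, and Sumo2 in raw counts, for each of the 12 libraries, with points for libraries and the mean ± SD of 3 beside them. Nedd8 reached 410 CPM in NEDD8 Cre-positive library 1 against 164 and 153 CPM in the others, and Sumo2 had 1 read in the SUMO2 libraries labelled Cre-negative and 9 in those labelled Cre-positive.

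The NEDD8 comparison asked how skin changes when Nedd8 is deleted in K14-expressing keratinocytes. Krt6a (chromosome 15, 101598345 to 101602742), a keratin of wounded epidermis, rose 111-fold, from 162 ± 29.0 to 18000 ± 2680 CPM (edgeR adjusted p = 5.27e-05). Gsta4 (chromosome 9, 78099229 to 78116631), a detoxifying enzyme induced by the oxidative stress factor NRF2, rose 352-fold, from 2.79 ± 0.766 to 988 ± 118 CPM (adjusted p = 4.82e-05). The differentiation keratin Krt10 fell from 5910 ± 3630 to 33.0 ± 18.0 CPM, 181-fold lower (adjusted p = 0.000376). Krt15 (chromosome 11, 100022584 to 100026754), a keratin of basal and hair follicle stem cells, fell from 1920 ± 228 to 27.4 ± 7.34 CPM, 69.6-fold lower (adjusted p = 5.27e-05), while the basal keratin Krt14 rose 6.41-fold, from 2570 ± 567 to 16500 ± 3420 CPM (adjusted p = 0.00114).

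Of 14045 genes tested with edgeR, 2238 rose and 2527 fell in Cre-positive skin, and 6358 had an unadjusted p under 0.05. The groups did not overlap for 7111 genes, 50.6% of those tested, where chance gives 10% on average over all ways to group the 6 libraries. More than 4-fold rises numbered 626 and falls 1072. Leaving out Cre-negative library 1 left 1318 rises and 1593 falls, leaving out Cre-negative library 2 left 1168 and 1485, and leaving out Cre-positive library 3 left 1674 falls. By Ddx3y and Xist counts, Cre-negative libraries 1 and 2 were male while Cre-negative library 3 and all 3 Cre-positive libraries were female. With that sex pattern as a covariate 476 genes rose and 906 fell. In the 4 female-pattern libraries, with the lone Cre-negative library assumed to vary like the others, 154 rose and 310 fell, and 458 of these were among the 4765 genes called with all 6 libraries, none with a changed sign. Of the 165 genes named for this line 56 lost their call with the covariate and 95 in the female-pattern libraries.

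Of the 8 largest fitted rises, 7 were in genes without counts in Cre-negative skin, so their sizes are lower bounds. Spink12, a protease inhibitor, was at least 783-fold higher, at 49.1 ± 12.4 CPM in Cre-positive skin. The cytokine Il24 was at least 518-fold higher, Dynap at least 460-fold, Sptssb at least 292-fold, the keratin Krt76 at least 268-fold, Gcnt3 at least 225-fold and Ces1h at least 205-fold, each against a floor of 3 counts over the group. Cxcl5, which draws neutrophils, had 1 count in Cre-negative and 1392 in Cre-positive skin, a ratio of 1400 (95% counting interval 251 to 55400). Among the falls, Far2, which makes fatty alcohols for sebum, had 7711 counts in Cre-negative and 1 in Cre-positive skin, 7660 times lower (1380 to 303000). The keratin Krt77 fell from 12400 ± 3670 to 5.41 ± 5.30 CPM, 2320-fold lower (edgeR adjusted p = 0.000271). No reads were left in Cre-positive skin for AAdacl4fm3 (at least 703-fold lower), Serpinb6d (357-fold), Skint5 (296-fold), Serpina3j (257-fold), Skint6 (220-fold) and Aadacl2fm2 (215-fold). Reads of near-identical family members, among them Sprr2, Lce1, Skint5 and Skint6, Serpinb, Stfa, Aadacl, H2 and Gsta genes, may be shared or lost in counting.

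Genes of epidermal alarm and repair rose. Among 37 tested alarmin and stress keratin genes 30 rose, 3 fell and 4 were not called, with 31 and 3 when adjusted over the list alone. Their median log2 fold change was 4.81 (camera adjusted p = 6.31e-16, adjusted p = 0.29 with an estimated correlation). Slpi, an antiprotease, rose 933-fold to 2100 ± 657 CPM, Sprr2b rose 204-fold, and the antimicrobial peptide gene Defb4 went from 2 to 1976 counts, a ratio of 994 (275 to 8210). Wound edge and migration genes rose in 14 of 21 cases, with 2 falls and 5 not called, and in 15 with 2 falls when adjusted over the list alone (median 2.58, camera adjusted p = 1.15e-07, adjusted p = 0.29 with an estimated correlation). Sprr1b, a precursor of the cornified envelope, rose 27.6-fold and the collagenase Mmp13 47.7-fold. Of 14 neutrophil genes 12 rose, 1 fell and 1 was not called, the same counts when adjusted over the list alone (median 4.22, camera adjusted p = 3.82e-07, adjusted p = 0.29 with an estimated correlation). With edgeR folds their median was 4.81, and 4.65 with genes at 0 set to their bound. Mmp9 rose from 13.6 ± 4.90 to 146 ± 72.1 CPM and Hdc from 2.95 ± 0.558 to 38.0 ± 4.0 CPM.

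Inflammatory cytokine genes moved up with them. In the cytokine and chemokine list 14 of 29 genes rose, 1 fell and 14 were not called, and 15 rose and 2 fell when adjusted over the list alone (median 1.32, camera adjusted p = 0.00299, adjusted p = 0.447 with an estimated correlation). The neutrophil attractant Cxcl2 rose 56.7-fold and the alarm cytokine Il33 10.4-fold, from 18.6 ± 1.30 to 193 ± 82.5 CPM, whereas Ccl27a, which draws T cells to resting skin, fell from 87.9 ± 34.1 to 3.74 ± 1.29 CPM, 24.2-fold lower. The list of secreted senescence factors and cell cycle arrest had 9 rises, 4 falls and 6 not called, the same rises and falls when adjusted over the list alone (median 1.32, camera adjusted p = 0.0132, adjusted p = 0.371 with an estimated correlation). Mmp3 rose 14.5-fold. The NF-kB list was not called (5 rose, 3 fell, 11 not called, camera adjusted p = 0.351), although Bcl3 rose 8.94-fold and Ptgs2 75.7-fold. The edgeR median of that list, 0.09, was 0.00 under upper-quartile scaling. The sex pattern of the libraries runs along with these groups. In the female-pattern libraries only, a fit with 1 Cre-negative library, Il33, Mmp3, Bcl3 and Ptgs2 lost their calls. Ptgs2 also lost its call with sex as a covariate (edgeR adjusted p = 0.0586). Over all 17 alternatives the log2 fold changes lay between 3.08 and 3.70 for Il33 and between 3.20 and 4.21 for Mmp3. They lay between 2.82 and 3.39 for Bcl3 and between 5.18 and 6.98 for Ptgs2, so a lost call was not a lost rise. Cxcl2 and Ccl27a kept their calls in all 17 alternatives.

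Oxidative and protein stress genes also rose. Of 24 NRF2 targets 19 rose, 1 fell and 4 were not called, with 19 and 1 when adjusted over the list alone (median 2.36, camera adjusted p = 1.23e-11, adjusted p = 0.29 with an estimated correlation). Srxn1 rose 44.0-fold, from 50.2 ± 1.61 to 2210 ± 46.8 CPM, the quinone reductase Nqo1 27.9-fold and Akr1b8 33.2-fold. Proteasome subunits rose in 18 of 31 cases with none falling and 13 not called, and in 22 when adjusted over the list alone (median 0.99, camera adjusted p = 1.26e-07, adjusted p = 0.29 with an estimated correlation). Psmb5, a catalytic subunit, rose 2.79-fold to 128 ± 25 CPM. Among 15 heat shock genes 8 rose and 7 were not called, with 9 rises when adjusted over the list alone (median 0.86, camera adjusted p = 0.00196, adjusted p = 0.317 with an estimated correlation), and the chaperone Hsp90aa1 rose 4.90-fold, from 209 ± 23.1 to 1020 ± 143 CPM. The unfolded protein and amino acid stress list had 11 rises, 3 falls and 6 not called, with 11 and 4 when adjusted over the list alone (median 0.89, camera adjusted p = 0.0177, adjusted p = 0.29 with an estimated correlation). The cystine transporter Slc7a11, also an NRF2 target, rose 304-fold, from 2.26 ± 1.45 to 678 ± 390 CPM. Cholesterol synthesis genes rose in 17 of 23 cases with 1 fall and 5 not called, and in 19 with 1 fall when adjusted over the list alone (median 1.33, camera adjusted p = 2.34e-06, adjusted p = 0.29 with an estimated correlation), Fdps rising 3.49-fold.

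Cell cycle genes rose without a single called fall. Of 30 G2 and M phase genes 25 rose and 5 were not called, with 27 rises when adjusted over the list alone (median 1.90, camera adjusted p = 1.52e-12, adjusted p = 0.294 with an estimated correlation). The mitotic kinase Aurka rose 7.81-fold, from 5.05 ± 0.729 to 39.4 ± 7.27 CPM, and Cdc20 5.82-fold. Of 30 S phase genes 17 rose and 13 were not called, with 19 rises when adjusted over the list alone (median 1.20, camera adjusted p = 4.92e-08, adjusted p = 0.294 with an estimated correlation). Cyclin E1, a substrate of a cullin-RING ligase, rose at the transcript level (Ccne1 8.23-fold, from 1.98 ± 0.0985 to 16.1 ± 5.10 CPM), as did Rrm2, 10.3-fold. In the neddylation pathway itself 7 genes rose, 1 fell and 13 were not called, the same counts of rises and falls when adjusted over the list alone (median 0.27, camera adjusted p = 0.0484, adjusted p = 0.29 with an estimated correlation). That call was lost without Cre-negative library 1 (0.0617), Cre-negative library 2 (0.0816) or Cre-positive library 1 (0.087), and with replicate numbers as blocks (0.0839). Ube2m, which carries NEDD8 to cullins, rose 2.69-fold, from 30.6 ± 0.290 to 82.1 ± 9.96 CPM.

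Sebaceous gland genes fell. Of 23 sebaceous gland genes 14 fell and 9 were not called, with 14 falls and 1 rise when adjusted over the list alone (median -2.85, camera adjusted p = 1.26e-07, adjusted p = 0.29 with an estimated correlation). Scd3 fell from 455 ± 197 to 6.08 ± 0.671 CPM, 74.2-fold lower, and the wax synthase Awat1 was 487-fold lower. Differentiation and barrier lists went in both directions, and camera did not call them: 12 of 43 granular layer genes rose and 19 fell (adjusted p = 0.101), 4 of 22 spinous genes rose and 6 fell (0.755), 6 of 25 barrier lipid genes rose and 7 fell (0.958), and 7 of 16 basal genes rose and 5 fell (0.364). The granular layer list passed without Cre-positive library 1 (0.0459) or Cre-positive library 3 (0.0354). Flg2, a filaggrin relative of the cornified layer, was 79.7-fold lower and Fa2h, which makes hydroxylated ceramides, 810-fold lower, whereas the desmosomal Dsc2 rose 32.3-fold and Cers3, which makes barrier ceramides, 5.22-fold. Hair follicle stem cell genes fell in 11 of 21 cases and rose in 4 (camera adjusted p = 0.101), with Lgr5 6.05-fold and Lgr6 5.75-fold lower. In the female-pattern libraries only, a fit with 1 Cre-negative library, Lgr5, Lgr6 and Cers3 lost their calls, but their folds held. Over all 17 alternatives the log2 fold changes lay between -2.85 and -2.41 for Lgr5, -2.88 and -2.36 for Lgr6, and 2.13 and 2.53 for Cers3. Krt15 was called in all 17 alternatives, with log2 fold changes from -6.25 to -5.90.

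Genes of antigen presentation and of resident immune cells fell. In the interferon gamma and antigen presentation list 18 of 26 genes fell and 8 were not called, with 20 falls and 1 rise when adjusted over the list alone (median -1.73, camera adjusted p = 1.22e-07, adjusted p = 0.317 with an estimated correlation). The class II gene H2-Aa fell from 78.9 ± 21.6 to 5.76 ± 0.971 CPM, 13.6-fold lower, and its transactivator Ciita was 19.2-fold lower. Dendritic and Langerhans cell genes fell in 9 of 13 cases with 1 rise and 3 not called, and in 12 with 1 rise when adjusted over the list alone (median -2.36, camera adjusted p = 0.000209, adjusted p = 0.317 with an estimated correlation). Cd207, the langerin of Langerhans cells, went from 393 counts to 0, at least 139-fold lower, and Mgl2 was 18.5-fold lower. T and NK cell genes fell in 10 of 16 cases with 1 rise and 5 not called, the same rises and falls when adjusted over the list alone (median -2.85, camera adjusted p = 0.000437, adjusted p = 0.29 with an estimated correlation), Il7r being 4.76-fold and Il2rb 7.20-fold lower. The type I interferon list was not called (1 rose, 5 fell, 16 not called, median -0.80, camera adjusted p = 0.0761) but passed without Cre-negative library 2 (0.0149). Macrophage genes were not called either (2 rose, 4 fell, 15 not called, camera adjusted p = 0.169), although Ccr2 was 9.62-fold lower.

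Genes of the tissue under the epidermis fell too. Of 24 skeletal muscle genes 19 fell and 5 were not called, with 21 falls when adjusted over the list alone (median -2.24, camera adjusted p = 1.15e-07, adjusted p = 0.317 with an estimated correlation), and Myh4 fell from 2490 ± 1690 to 268 ± 89.8 CPM. Adipocyte genes fell in 7 of 18 cases and 11 were not called, with 11 falls when adjusted over the list alone (median -1.40, camera adjusted p = 0.000437, adjusted p = 0.414 with an estimated correlation), Car3 falling from 1170 ± 405 to 146 ± 31.6 CPM. Fibroblast and matrix genes fell in 9 of 26 cases with 1 rise and 16 not called, the same rises and falls when adjusted over the list alone (median -0.62, camera adjusted p = 0.0207, adjusted p = 0.49 with an estimated correlation). That call was lost without Cre-negative library 3 (0.0556) or Cre-positive library 2 (0.0943), and Col1a2 was 2.88-fold lower, at 269 ± 85.5 CPM. Mitochondrially encoded genes had 3 falls of 9 and 6 not called, also 3 when adjusted over the list alone (median -1.09, camera adjusted p = 0.0204, adjusted p = 0.513 with an estimated correlation), and fry did not call them (0.0657). Endothelial genes were not called (5 rose, 1 fell, 15 not called, camera adjusted p = 0.364). Of the 42 lists tested 13 were called up and 8 down, and 0 of these 21 calls held in camera with an estimated correlation. The directional fry test asks whether a list changed at all, not whether it changed more than the other genes. It called 20 of these 21 lists, all but the mitochondrially encoded one, and 4 that camera did not: hair follicle stem cells (0.0123), Wnt and Shh signalling (0.0223), melanocytes (0.0396) and HIF targets (0.046). The fall of muscle and fat markers and the sex pattern run along with the Cre groups, so they accompany every group of genes above.

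**Figure D2:**
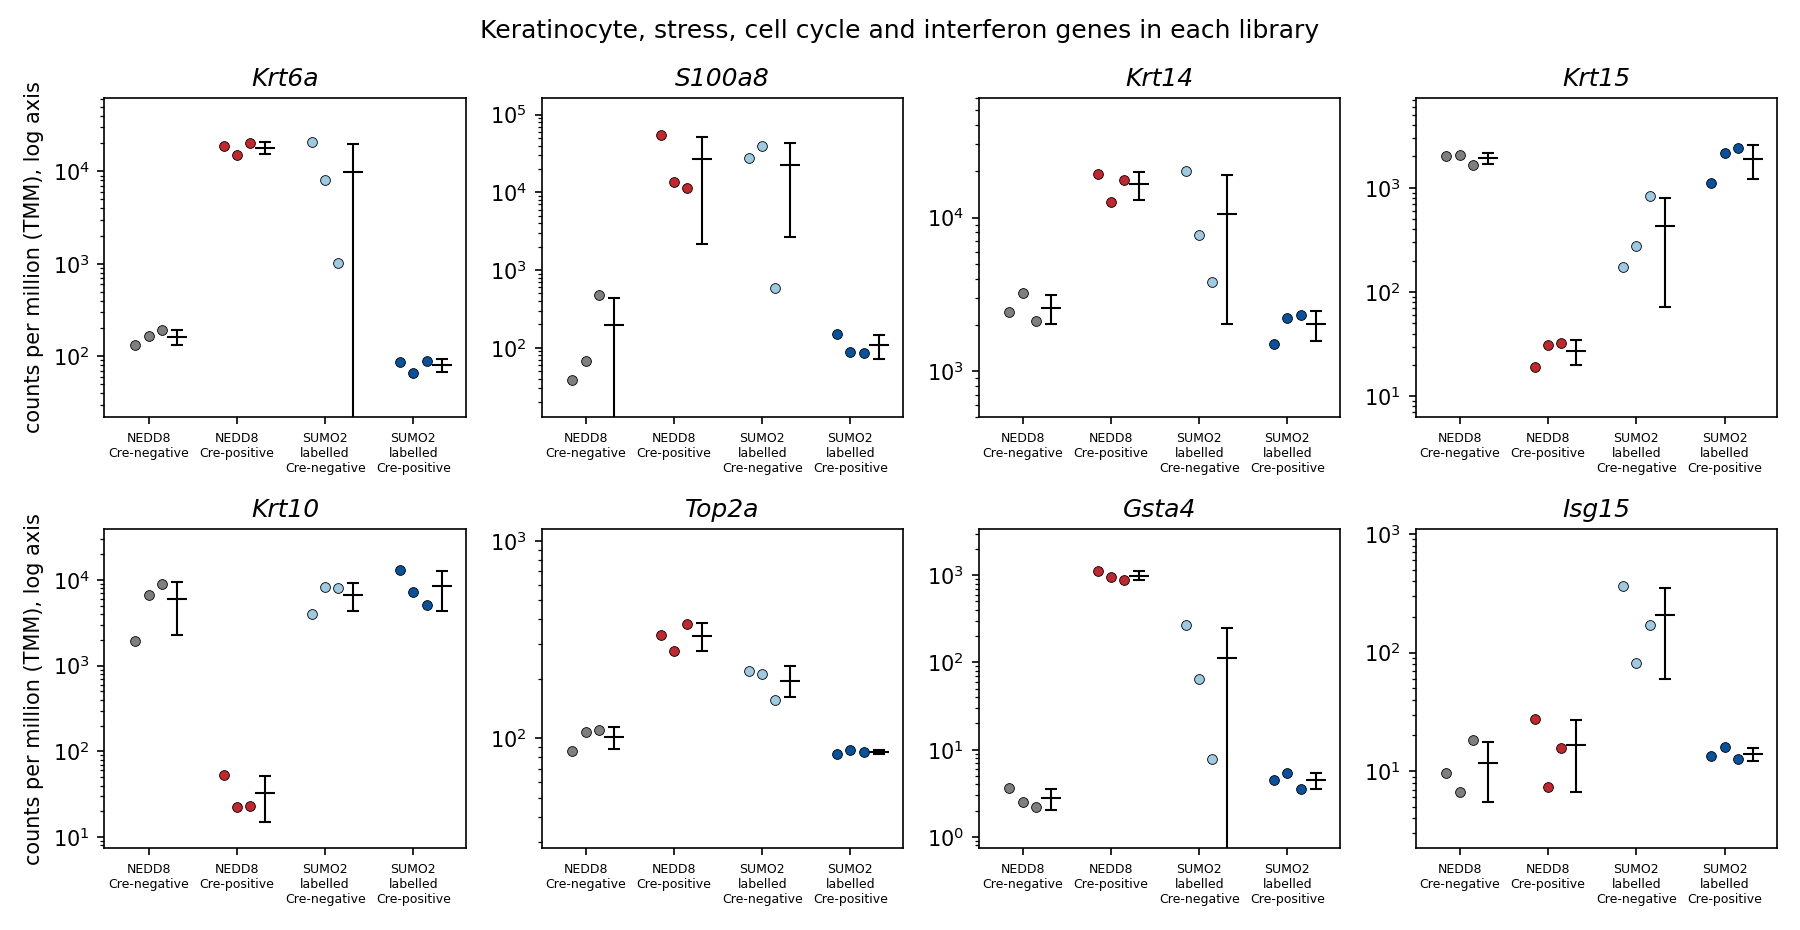
CPM of 8 genes in each library on a log axis, with points for the 12 libraries and the mean ± SD of 3 beside each group (the lower bar runs to the foot of the axis where the SD exceeds the mean). Krt6a stood at 18000 ± 2680 CPM in NEDD8 Cre-positive skin and at 9920 ± 9980 CPM in the SUMO2 libraries labelled Cre-negative.

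The SUMO2 comparison asked the same of Sumo2. Stress and inflammation genes had higher values in the libraries labelled Cre-negative, but no gene passed the test. S100a8 (chromosome 3, 90576285 to 90577342), a neutrophil and keratinocyte alarmin, stood at 22700 ± 20000 CPM in the libraries labelled Cre-negative and 109 ± 37.6 CPM in those labelled Cre-positive (edgeR adjusted p = 0.162). Krt6a stood at 9920 ± 9980 and 80.4 ± 12.4 CPM (adjusted p = 0.129), and the interferon-stimulated gene Isg15 at 206 ± 146 and 13.9 ± 1.75 CPM (adjusted p = 0.111). Top2a, a gene of dividing cells, stood at 196 ± 35.0 and 85.2 ± 1.82 CPM (adjusted p = 0.119), whereas the muscle actin Acta1 was lower in the libraries labelled Cre-negative, 1610 ± 1430 against 4570 ± 1520 CPM. Directions here and below follow the labels, which were not reassigned.

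Of 12951 genes tested, edgeR called 0 higher and 0 lower in the libraries labelled Cre-positive, and 2003 had an unadjusted p under 0.05, of which 811 were higher and 1192 lower. DESeq2 called 113 and 333, and limma-voom with quality weights 649 and 706. The groups did not overlap for 2720 genes, 21% of those tested, where chance gives 10% on average over all ways to group the 6 libraries. As genes are not independent, a single grouping can lie far from that average without any effect of Cre. The library labelled Cre-negative 3 stood apart from the others of its label: S100a8 reached 590 CPM there against 27700 and 39700, and Krt6a 1030 against 20700 and 8000. Without it edgeR called 1068 genes higher and 1140 lower in the libraries labelled Cre-positive, and 30 of the 86 named genes passed. Without the library labelled Cre-negative 2, 0 were higher and 1 lower. The smallest adjusted p belonged to Fxyd4, an ion transport regulator, at 55.8 ± 26.8 and 0.991 ± 0.371 CPM (0.0545). It was followed by Car12 (52.1 ± 5.34 and 15.3 ± 2.34 CPM), Klk6 (316 ± 142 and 18.5 ± 8.13 CPM), Prss22 (53.8 ± 26.2 and 5.78 ± 0.656 CPM) and Sprr2a3 (23.6 ± 11.2 and 1.75 ± 1.04 CPM), each at an adjusted p of 0.111 and each higher in the libraries labelled Cre-negative. All 6 SUMO2 libraries had the male pattern of Ddx3y and Xist.

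Camera called 22 of 42 lists between the SUMO2 groups, 6 higher and 16 lower in the libraries labelled Cre-positive, although 0 of their members was called over all genes. None of these lists was called with an estimated correlation or by the directional fry test. All 30 G2 and M phase genes had lower values in the libraries labelled Cre-positive, and 25 were called lower when adjusted over the list alone (median -1.08, camera adjusted p = 2.07e-17, adjusted p = 0.421 with an estimated correlation). For S phase genes 6 of 30 were lower when adjusted over the list alone (median -0.76, camera adjusted p = 1.12e-08, adjusted p = 0.421 with an estimated correlation). Alarmins and stress keratins had 26 lower and 1 higher of 32 when adjusted over the list alone (median -3.89, camera adjusted p = 5.55e-17, adjusted p = 0.421 with an estimated correlation). All 24 type I interferon stimulated genes had lower values in the libraries labelled Cre-positive, 10 of them called lower when adjusted over the list alone (median -1.20, camera adjusted p = 6.54e-10, adjusted p = 0.421 with an estimated correlation). Bst2, an antiviral membrane protein of that list, stood at 113 ± 48.0 CPM in the libraries labelled Cre-negative and 36.0 ± 9.92 CPM in those labelled Cre-positive. Isg15 passed without the library labelled Cre-negative 2 (0.046) or Cre-negative 3 (0.00691), and its adjusted p ranged from 4.21e-12 to 0.587 over 15 alternatives.

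Further lists had lower values in the libraries labelled Cre-positive, with fewer or no members passing when adjusted over the list alone. Wound edge genes had 9 lower (median -0.81, camera adjusted p = 6.34e-06, adjusted p = 0.421 with an estimated correlation) and HIF targets, which respond to low oxygen, 4 lower (median -0.64, camera adjusted p = 0.000181, adjusted p = 0.421 with an estimated correlation). Proteasome subunits had 0 (median -0.29, camera adjusted p = 0.000144, adjusted p = 0.53 with an estimated correlation), immediate early genes 3 lower (median -0.37, camera adjusted p = 0.00244, adjusted p = 0.421 with an estimated correlation) and inflammatory cytokines 5 lower (median -0.90, camera adjusted p = 0.00442, adjusted p = 0.421 with an estimated correlation). The p53 targets had 1 higher and 1 lower (median -0.41, camera adjusted p = 0.00724, adjusted p = 0.421 with an estimated correlation), NF-kB genes 4 lower (median -0.25, camera adjusted p = 0.00732, adjusted p = 0.421 with an estimated correlation) and neutrophil genes 1 higher and 4 lower (median -1.23, camera adjusted p = 0.00948, adjusted p = 0.421 with an estimated correlation). For cholesterol synthesis no gene passed (median -0.32, camera adjusted p = 0.00265, adjusted p = 0.495 with an estimated correlation), and the call was lost without the library labelled Cre-negative 1 (0.0925).

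In the same direction lay melanocyte genes, 5 of 6 of them lower when adjusted over the list alone (median -2.57, camera adjusted p = 0.028, adjusted p = 0.519 with an estimated correlation), a call lost without the library labelled Cre-positive 1 (0.101). The melanin enzyme gene Dct stood at 359, 370 and 18.7 CPM in the libraries labelled Cre-negative and at 26.7, 25.1 and 28.2 CPM in those labelled Cre-positive. Retroviral sensing and cell death genes had 0 passing (median -0.38, camera adjusted p = 0.0283, adjusted p = 0.421 with an estimated correlation), lost without the library labelled Cre-negative 3 (0.0886). Granular layer genes had 11 lower (median -0.26, camera adjusted p = 0.0402, adjusted p = 0.601 with an estimated correlation), lost without the library labelled Cre-negative 2 (0.133), Cre-negative 3 (0.188), Cre-positive 2 (0.188) or Cre-positive 3 (0.0568).

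Genes of muscle, sebum, hair and T cells had higher values in the libraries labelled Cre-positive. Of 24 muscle genes 23 were higher, with 0 passing when adjusted over the list alone (median 1.83, camera adjusted p = 8.85e-12, adjusted p = 0.421 with an estimated correlation). Hair shaft genes had 1 higher when adjusted over the list alone (median 1.62, camera adjusted p = 0.000909, adjusted p = 0.443 with an estimated correlation), lost without the library labelled Cre-negative 3 (0.0886). Sebaceous genes (median 0.85, camera adjusted p = 0.00121, adjusted p = 0.539 with an estimated correlation) and T and NK cell genes (median 1.61, camera adjusted p = 0.00837, adjusted p = 0.539 with an estimated correlation) had 0 passing when adjusted over the list alone, and both calls were lost without the library labelled Cre-negative 1 (0.113 and 0.122). Mitochondrially encoded genes (median 0.74, camera adjusted p = 0.00732, adjusted p = 0.443 with an estimated correlation) and adipocyte genes (median 0.39, camera adjusted p = 0.0334, adjusted p = 0.539 with an estimated correlation) also had 0, and the adipocyte call was lost without the library labelled Cre-negative 1 (0.126), Cre-negative 2 (0.123), Cre-positive 2 (0.0951) or Cre-positive 3 (0.111). NRF2 targets (median -0.21, camera adjusted p = 0.419) and the interferon gamma list (median 0.00, camera adjusted p = 0.951) were not called.

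The last comparison asked whether the responses, Cre-positive minus Cre-negative as labelled, differ between the lines. The NRF2 target Srxn1 rose 44.0-fold in NEDD8 Cre-positive skin, and its log2 response exceeded the SUMO2 response by 6.18 (SE 0.4, edgeR adjusted p = 5.04e-06). Gpx2, a glutathione peroxidase, differed by 10.90 (SE 0.684, adjusted p = 5.04e-06), and the epidermal growth factor family member Hbegf by 7.86 (SE 0.595, adjusted p = 1.42e-05). Krt15 differed by -8.21 (SE 0.782, adjusted p = 5.42e-05) and Sostdc1, a BMP and WNT antagonist, by -4.77 (SE 0.351, adjusted p = 1.24e-05). Of 13981 genes tested in all 12 libraries, edgeR called 2678 with the higher response in NEDD8 skin and 2361 with the higher response in SUMO2 skin, and 6457 had an unadjusted p under 0.05. Upper-quartile scaling moved the median of all differences by -0.17 and gave 2236 and 2769.

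Across the 12803 genes tested in both lines the log2 responses ran against each other (Pearson's r = -0.66, Spearman's rho = -0.64, over genes, which are not independent replicates). Without the SUMO2 library labelled Cre-negative 1 Pearson's r was -0.53. Of 1979 genes that rose in NEDD8 skin 1811 had a negative SUMO2 fold as labelled, and of 2359 that fell 2029 had a positive one, while 51.0% of all genes had a negative one. With edgeR no called gene was shared because SUMO2 had 0 calls (2003 at an unadjusted p under 0.05). With DESeq2 272 genes were called higher in NEDD8 Cre-positive skin and lower in the SUMO2 libraries labelled Cre-positive, where independence gives 62.4 (Fisher's exact p = 4.38e-143), and 91 the other way round, where it gives 22.6 (Fisher's exact p = 9.61e-44). In the same direction 1 was shared higher and 2 lower, where independence gives 21.5 and 65.6. The Fisher p-values also count genes as if they were independent, and they do not measure the spread between samples.

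Camera called 22 of 43 lists for a difference, 14 with the higher response in NEDD8 skin and 8 with the higher response in SUMO2 skin, and none with an estimated correlation. All 30 G2 and M phase genes were called higher in the NEDD8 response, also when adjusted over the list alone (median 3.10, camera adjusted p = 1.16e-15, adjusted p = 0.294 with an estimated correlation). Of 38 alarmin genes 34 were higher, 3 lower and 1 not called, with 35 and 3 when adjusted over the list alone (median 9.14, camera adjusted p = 5.19e-15, adjusted p = 0.32 with an estimated correlation). Of 24 NRF2 targets 16 were higher, 1 lower and 7 not called, with 17 and 1 when adjusted over the list alone (median 2.53, camera adjusted p = 3.86e-08, adjusted p = 0.294 with an estimated correlation). Proteasome subunits were higher in 23 of 31 cases with 8 not called, and in 27 when adjusted over the list alone (median 1.40, camera adjusted p = 2.25e-08, adjusted p = 0.294 with an estimated correlation). Of 24 muscle genes 20 were lower in the NEDD8 response and 4 not called, with 22 when adjusted over the list alone (median -3.99, camera adjusted p = 5.86e-09, adjusted p = 0.351 with an estimated correlation). Sebaceous genes were lower in 14 of 25 cases with 11 not called, the same 14 falls when adjusted over the list alone (median -3.62, camera adjusted p = 4.91e-06, adjusted p = 0.351 with an estimated correlation). The type I interferon list was not called (6 higher, 0 lower, 20 not called, camera adjusted p = 0.178). As the direction of the SUMO2 response rests on its labels, so do the sizes and calls of these differences. With exchanged labels the called lists above kept their sign. Alarmins (median 0.85, camera adjusted p = 0.089) and muscle genes (median -0.29, camera adjusted p = 0.425) were then no longer called. The type I interferon list turned its sign, to a median of -1.88. Sex enters these differences too, since it ran along with the Cre groups in NEDD8 skin while all SUMO2 libraries were male. No fit of the difference took sex into account. With the labels as given, 4 of 6 sex-linked genes were called lower in the NEDD8 response and 2 were not called.

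**Figure D3:**
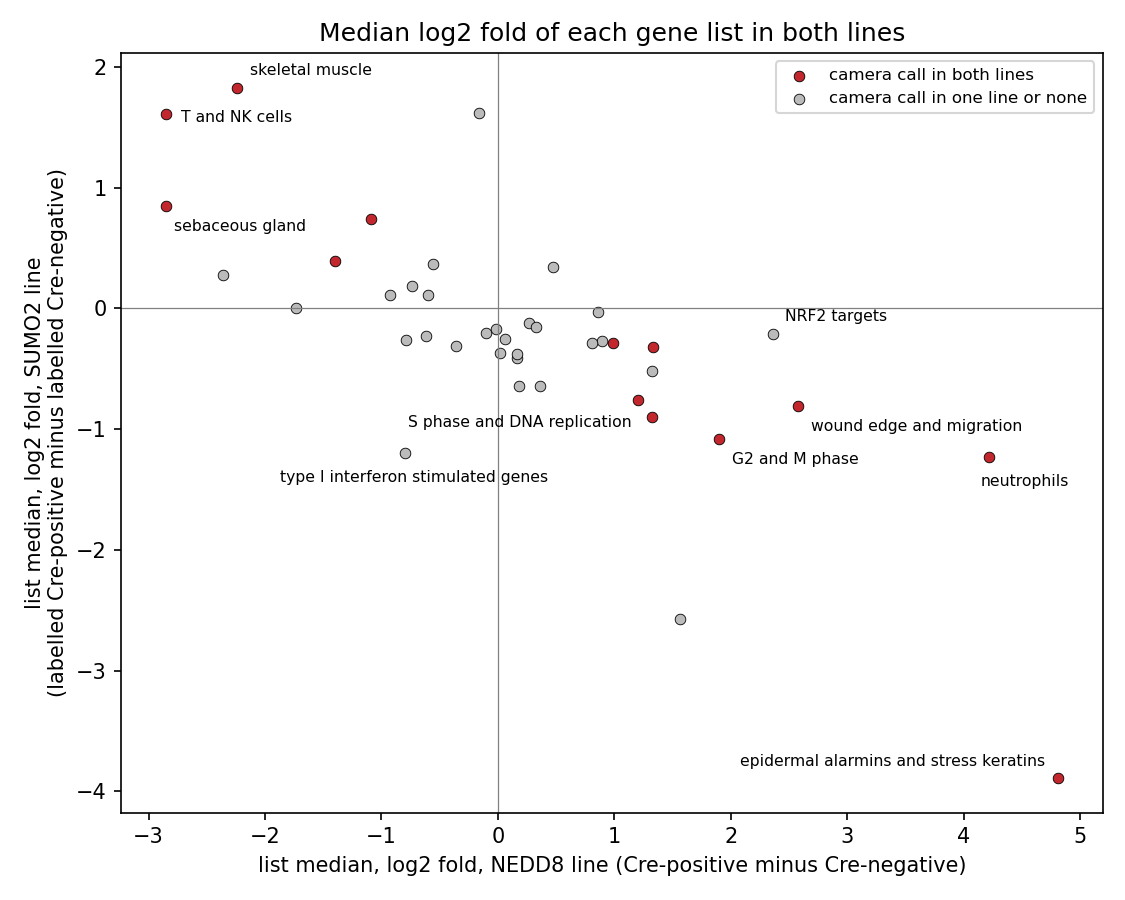
Median log2 fold change of each gene list, Cre-positive minus Cre-negative as labelled, in NEDD8 skin on the horizontal axis and SUMO2 skin on the vertical axis, with 1 point per list, red where camera called the list in both lines. Alarmins and stress keratins lie at 4.81 and -3.89, and skeletal muscle at -2.24 and 1.83.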

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

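The tests of label exchange, of a deviating library, of dilution by keratinocyte RNA and of less muscle and fat were chosen after the results were seen.

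The responses of the lines, Cre-positive minus Cre-negative as labelled, were compared directly, and that test of the difference picked out the results in this and the next paragraph. It called 2678 genes with the higher response in NEDD8 skin and 2361 with the higher response in SUMO2 skin. Among 100 drawn splits of the libraries within each line, 1, the real split, gave as many genes (5039). The highest other split gave 4140 and kept the NEDD8 groups while mixing the SUMO2 groups. The 100 splits cross the groupings of both lines, and each line alone has only 10 splits, too few for a share under 0.05. The share of 1 in 100 therefore does not exclude a grouping by chance for the NEDD8 part or for the SUMO2 part of the difference. The log2 differences were 10.90 for Gpx2, 6.18 for Srxn1, 7.86 for Hbegf and 9.95 for Fxyd4, which encode redox enzymes, a growth factor and an ion transport regulator. They were -4.77 for Sostdc1, -7.81 for the hair keratin Krt32, -6.80 for Arhgef26, -8.21 for Krt15 and -7.88 for Serpinb7. The sperm flagellum gene Tekt5 gave a fitted value of 9.72, which rests on 3 counts in the SUMO2 libraries labelled Cre-positive against 33 in those labelled Cre-negative, and on 37 and 2894 counts in NEDD8 Cre-negative and Cre-positive skin.

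The lists with the higher response in NEDD8 skin had median log2 differences of 9.14 (alarmins and stress keratins), 7.57 (neutrophils), 3.95 (inflammatory cytokines), 3.8 (wound edge), 3.10 (G2 and M phase), 2.53 (NRF2 targets), 2 (secreted senescence factors), 1.85 (S phase), 1.85 (cholesterol synthesis), 1.40 (proteasome), 1.22 (unfolded protein and amino acid stress), 0.88 (heat shock), 0.85 (HIF targets) and 0.45 (neddylation). Those with the higher response in SUMO2 skin had -4.21 (T and NK cells), -4.09 (hair shaft), -3.99 (muscle), -3.62 (sebaceous gland), -2.59 (dendritic and Langerhans cells), -1.83 (adipocytes), -1.57 (interferon gamma and antigen presentation) and -1.36 (mitochondrially encoded genes). The HIF call was lost without the SUMO2 library labelled Cre-negative 3 (camera adjusted p = 0.0709). The hair shaft call was lost without NEDD8 Cre-negative 1 (0.0681), NEDD8 Cre-positive 1 (0.0529) or the SUMO2 libraries labelled Cre-negative 3 (0.0725) or Cre-positive 2 (0.0667). Of its 26 genes 5 were lower in the NEDD8 response, 1 higher and 20 not called, and fry did not call it (adjusted p = 0.0885). Fewer of its genes passed the filter in the separate fits, 13 in NEDD8 skin (median -0.16) and 21 in SUMO2 skin (median 1.62). The neddylation call was lost without NEDD8 Cre-negative 2 (0.0567), NEDD8 Cre-positive 1 (0.0928) or the SUMO2 libraries labelled Cre-negative 1 (0.0575) or Cre-negative 2 (0.0509).

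Alarmin, interferon and cell cycle genes had higher values in the SUMO2 libraries labelled Cre-negative than in those labelled Cre-positive. A single deviating library is argued against as the whole cause. With any library left out, the edgeR median log2 fold change stayed at or below -3.53 for alarmins. For interferon genes the edgeR median lay between -1.49 and -0.71, the last value without the library labelled Cre-negative 1. The voom median of G2 and M phase lay between -1.20 and -0.93. By log CPM, however, the library labelled Cre-negative 3 correlated better with the libraries labelled Cre-positive (0.951 to 0.962) than with its own label (0.895 and 0.907). An exchange of the group labels stays open. The Sumo2 read rate in the libraries labelled Cre-negative was 0.0781 times that in the libraries labelled Cre-positive (0.00178 to 0.564). This rests on 10 reads, reads lost to the copies of Sumo2 are not excluded, and the floxed exons are not given. In the NEDD8 line, where Sumo2 was not targeted, Cre-negative over Cre-positive was 1.9 (1.06 to 3.51). Taken instead as the libraries with the higher alarmin values over the others, the NEDD8 ratio is 0.525, which the SUMO2 interval includes. An inflamed state of the mice labelled Cre-negative, or a difference in muscle content between the samples, may also be at work and was not tested. All 10 splits of the 6 libraries gave as many genes as the real value of 0, the highest other being 0, and 10 splits are too few for a share under 0.05.

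In NEDD8 skin 2 of the 3 Cre-negative libraries were male and all 3 Cre-positive ones female, so sex runs along with the deletion. Among 3183 genes called between the male controls and the Cre-positive libraries, the female control lay at a median position of 0.0843 between the male controls (0) and the Cre-positive libraries (1), with quartiles of -0.0535 and 0.237, and 94.9% of these genes lay nearer the male controls. That is 1 female control only, so sex cannot be told apart from the deletion gene by gene, and the deletion remains the explanation the design names. Of the 10 splits of the 6 libraries 1, the real one, gave as many calls (4765), the highest other gave 0, and 10 splits are too few for a share under 0.05. The 3 other splits that part all 3 numbered pairs gave 0, as did those that part 1 pair only.

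Muscle, fat, sebaceous, T and NK cell, and dendritic and Langerhans cell genes fell in NEDD8 Cre-positive skin, while neutrophil genes rose and the macrophage and mast cell lists were not called. Dilution by a larger share of keratinocyte RNA lowers all other cell types alike, but the endothelial median lay 2.73 above the muscle median (log2). The 95% bootstrap interval of 1.69 to 3.32 resampled the genes of both lists, not the samples. It therefore leaves out the spread between samples. The endothelial list also holds Selp, a gene of activated vessels that rose. The values thus argue against dilution as the whole cause for the genes of these lists only. For a sample with less muscle and fat below the skin, 52 genes of the sebaceous gland, T cells and Langerhans cells were pooled. Their median was -2.78 (quartiles -4.41 and -0.85). These lists were taken because they had fallen, and the sebaceous list shares Fabp4 with the adipocyte list. The value therefore restates the pattern and cannot decide whether such a sample accounts for it. For muscle and fat themselves the depth of sampling stays open, and loss of sebaceous, T and Langerhans cells or lower expression in them was not tested apart.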

How the results depend on the processing

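Sex as a covariate, female-pattern libraries only and exchanged SUMO2 labels were tested only after the results were seen. With exchanged labels 273 of the 5039 genes that differed kept their call and 610 changed sign, and Hbegf, Fxyd4, Tekt5 and Arhgef26 were no longer called. Under the other alternatives no named gene or list that passed its test changed sign, and the 10 genes named for the difference kept their call wherever they were tested. No alternative for the difference took sex into account. Where a count below moved by more than 1.5 times, the cause was not tested.

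For NEDD8, genes higher and lower numbered 476 and 906 with sex as a covariate and 154 and 310 in female-pattern libraries only. Leaving out each library in turn gave 1168 to 3226 higher and 1485 to 3371 lower. Of the 165 named genes 56 lost their call with the covariate and 95 in the female-pattern libraries. With replicate blocks none lost it, 2397 genes were higher and 2778 lower, and of 42 list results 1, neddylation, lost its call (0.0839) and no other changed.

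For SUMO2, where edgeR called 0 and 0, the counts higher and lower in the libraries labelled Cre-positive were 90 and 294 with no filter on low counts, 113 and 333 with DESeq2, 649 and 706 with limma-voom, and 21 and 204 with all 12 libraries in a joint fit. RLE scaling, a filter of at least 1 CPM in 3 libraries, and omission of muscle, fat, hair and blood genes gave 1 lower each. Replicate blocks gave 23 lower, but equal numbers correlated at only 0.00, -0.13 and 0.26, and Cre-negative 2 correlated best with Cre-positive 1 (0.42). Leaving out each library gave 0 to 1068 higher and 0 to 1140 lower. Another split of the SUMO2 libraries gave 2482 genes at an unadjusted p under 0.05 against 2003 for the real one, and it set the libraries labelled Cre-negative 3, Cre-positive 2 and Cre-positive 3 against the other 3, which points to a structure of these samples.

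The difference gave 114 and 201 genes with exchanged SUMO2 labels, 2035 to 3030 and 1873 to 2782 with each library left out, and 2560 and 2463 with replicate blocks. The correlation of the responses lay between -0.73 and -0.53 with each library left out and at -0.69 with blocks. The genes called higher in NEDD8 Cre-positive skin and lower in the SUMO2 libraries labelled Cre-positive numbered 0 with edgeR and 272 with DESeq2, where SUMO2 has calls to share. Upper-quartile scaling took the edgeR median of the NF-kB list in NEDD8 to 0.00. It turned the sign of the edgeR medians of immediate early genes in NEDD8 (-0.06) and heat shock genes in SUMO2 (0.01). In the difference it turned those of spinous (-0.05) and barrier lipid genes (-0.02). Sumo2 rests on 10 reads in the SUMO2 line, where depth and reads lost to its copies may both limit it.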

Other observations

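The test of interferon and NRF2 genes with exchanged SUMO2 labels was chosen after the results were seen.

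Some pigment cell genes were called in NEDD8 Cre-positive skin, in both directions. Dct, an enzyme of melanin synthesis, rose 3.6-fold, from 28.7 ± 4.03 to 104 ± 47.2 CPM (edgeR adjusted p = 0.00594), and Mlana and Tyrp1 rose 5.07-fold and 5.06-fold, while Mitf, the factor that drives them, was 2.33-fold lower, at 17.1 ± 2.21 CPM. Of 6 melanocyte genes 3 rose, 1 fell and 2 were not called, and camera did not call the list (adjusted p = 0.169). All 4 genes lost their calls in the female-pattern libraries only, a fit with 1 Cre-negative library, and Dct also in the joint fit of 12 libraries (0.0505). Their folds held over all 17 alternatives. The log2 fold changes lay between 1.53 and 2.17 for Dct, 2.13 and 2.98 for Mlana, 1.85 and 2.77 for Tyrp1, and -1.31 and -1.15 for Mitf. With sex as a covariate Dct (0.119), Tyrp1 (0.153) and Mitf (0.0501) lost theirs. In the list of retroviral sensing and cell death, the kinase gene Ripk3 rose 8.45-fold, from 0.784 ± 0.346 to 6.53 ± 0.704 CPM (adjusted p = 0.000954), and Mlkl, whose product opens the membrane, 21.5-fold, from 0.256 ± 0.244 to 5.18 ± 1.57 CPM (adjusted p = 0.00117). That list had 4 rises, 1 fall and 15 not called, and camera did not call it (adjusted p = 0.221). Ripk3 and Mlkl lost their calls in the female-pattern libraries only. Over all 17 alternatives their log2 fold changes lay between 2.50 and 3.43 and between 3.27 and 5.43.

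Single genes stood out in lists that were not called. The membrane protein gene Mal rose 156-fold, from 1.43 ± 0.405 to 222 ± 58.1 CPM, in the nerve and Schwann cell list (2 rose, 1 fell, 6 not called, median -0.74, mean 0.44). Rhox5, a homeobox gene in the list of germline genes (1 rose, 1 fell, 2 not called), went from 0 to 103 counts, at least 45.5-fold higher. The angiogenic peptide Adm rose 9.20-fold and the glucose transporter Slc2a1 2.87-fold in the HIF list (5 rose, 2 fell, 13 not called, camera adjusted p = 0.169). Among p53 targets 7 rose and 4 fell, with Bax 2.92-fold higher and Sesn1 5.39-fold lower. Selp, an adhesion molecule of activated vessels, rose 10.6-fold, and Bmp4, a signal of the hair follicle, was 7.80-fold lower. In the female-pattern libraries only, a fit with 1 Cre-negative library, Mal and Sesn1 kept their calls. Rhox5, Adm, Slc2a1, Bax, Selp and Bmp4 lost theirs there. Over all 17 alternatives the log2 fold changes lay between 2.94 and 3.49 for Adm, 1.34 and 1.66 for Slc2a1, and 1.25 and 1.81 for Bax. They lay between 2.63 and 3.77 for Selp and between -3.13 and -2.67 for Bmp4.

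A hypothesis of this re-analysis is that both lines share an inflamed epidermal state, to which, among other differences, NRF2 genes are added in the NEDD8 contrast and interferon genes in the SUMO2 contrast. It takes the SUMO2 contrast as libraries labelled Cre-negative minus those labelled Cre-positive, a direction the labels do not give. Taken so, edgeR called 114 genes higher in the NEDD8 contrast and 201 higher in the SUMO2 contrast, and 18 list results were split evenly, 9 and 9 of 43. NRF2 targets had a median log2 difference of 2.46 (camera adjusted p = 1.89e-20, adjusted p = 0.0204 with an estimated correlation), with 11 of 24 genes called higher, 0 lower and 13 not called, and 19 higher when adjusted over the list alone. Srxn1 differed by 4.84, Gpx2 by 6.44 and Sostdc1 by -4.17. Type I interferon genes had a median of -1.88 (camera adjusted p = 8.77e-10), with 0 higher, 4 lower and 22 not called, and 17 lower when adjusted over the list alone. Part of that median is the fall of the same list in NEDD8 skin (median -0.80). The interferon gamma list differed about as much (median -1.81, camera adjusted p = 5.31e-11) with a SUMO2 median of 0.00 and a NEDD8 median of -1.73, so such a difference need not come from the SUMO2 line. Lists outside the hypothesis differed as well, with adjusted p of 5.67e-08 for the proteasome, 2.1e-07 for G2 and M phase, 5.07e-06 for cholesterol synthesis and 6.35e-06 for heat shock. The shared state itself was not tested, since a list without a called difference, such as the alarmins (0.089), is not thereby shown to be alike. The NRF2 and type I interferon lists were picked because of what they had shown in each line, so these tests restate that observation. The hypothesis therefore stays open, the interferon part also for its camera adjusted p of 0.377 with an estimated correlation. All of it also stays open for the direction of the labels. The sex pattern of the NEDD8 libraries was not taken into account in this contrast either.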
